A study of Caenorhabditis elegans with 2 samples.

How the data were processed

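EFL-1 tagged with GFP was immunoprecipitated from young adult worms in 2 biological replicates, each with 1 technical replicate per the labels. The labels name a control experiment, and the text deposited with each sample lists a control alignment that both replicates share; neither was analysed here. Chromatin was fragmented by sonication, per the labels. The antibody is named after efl-1 in one label and described as directed against GFP in another; the description is followed here.

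The authors deposited narrowPeak lists on builds ce10 and ce11. For each build there is a list per replicate, called on the alignments of that replicate and the shared control, a list called on the alignments of both replicates together, and an optimal list thresholded by the irreproducible discovery rate (IDR), per the texts deposited with the samples. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' own, deposited in the seventh column, and its scale is not given in the sources used here. It was used to rank, filter and describe peaks within a list. Between replicates it was used for correlations and to give the values of single peaks side by side. The deposited −log10 q-value is the same, 3.88, for all 2825 optimal peaks and was therefore not used for ranking. The p-value column holds a placeholder in every row. The summit offset deposited for each region was added to its start to give the summit. Each replicate list and the joint list holds 30000 regions, background included, as the deposited lists are described as input to IDR. The optimal list was identical to the 2825 regions of highest signal in the joint list. The median width of the optimal peaks was 290 bp.

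The ce11 lists were used with the WBcel235 genome sequence and the Ensembl release 115 annotation, after checking that these are the same assembly and that all regions lie within its chromosomes. The ce10 lists were used only for counts of peaks. Regions on the mitochondrial genome were left out of every comparison, which leaves 2802 optimal peaks. Coordinates are counted from 1. A start site is the 5' end of any annotated transcript of a protein-coding gene (29314 sites of 19973 nuclear genes). A gene had a promoter peak when a summit was within 500 bp of one of its start sites, so that a peak between divergent genes counted for both. Where a gene had several promoter peaks, the values are those of the strongest. A replicate's value at a peak is that of its strongest overlapping region.

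Read counts per sample are not part of the lists used here, so depth is unknown, and the precision given is that of counts of peaks or genes. With 1 group of 2 replicates no test between groups was made. Shares have exact or Wilson 95% intervals and odds ratios have 95% intervals from Fisher's exact test, all for counting error only; genes and peaks are not independent replicates. Replicate overlap was counted over the 2802 strongest nuclear regions of each list with a minimum overlap of 1 bp and set against 1000 rotations of the positions within chromosomes. Rank agreement was tested with 100000 permutations of the pairing. The promoter share was set against 1000 random placements of the summits within their chromosomes. Gene lists, chromosomes and chromosome centres were tested with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 16 lists and over the 6 chromosomes. Motifs were counted on either strand within 100 bp of the summit and in flanks 400 to 500 bp away on both sides, with an exact binomial test on peaks that had the motif in only the centre or only the flank. Below, a peak contains or lacks TTSSCGC or TTYGAA by what lies within 100 bp of its summit, not by its whole width. For 7-mers the centre was 50 bp on either side and the flanks lay 400 to 450 bp away.

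The comparisons of the report, the lists and the rule for named genes were fixed before the data were examined, and the comparison with ribosomal protein genes, the joint group of somatic lists and the tests named as such in the closing parts were chosen afterwards. The rule names efl-1, dpl-1 and lin-35, the genes with the start site nearest to and within 500 bp of the 25 strongest summits, and in each list the 4 members with the strongest promoter peaks and the first 2 members without one in the order of the list. Genes named outside it were chosen after their values were seen, and 1 gene that the rule names is not reported here. The alternatives tried were other overlap rules, the 1401 strongest optimal peaks, windows of 200 and 1000 bp, the strongest regions of the joint list, the list of a single replicate, assignment to the nearest start site, autosomal genes alone, other motif forms and windows, and 6-mers. The outermost start site of each gene was added after the data were seen. On simulated peaks placed at 90 genes of a list, 93 genes of the list were found with a peak, since some random peaks fell near its other members, and 2 of 50 random lists had p under 0.05. A motif planted in 29.6% of 1800 simulated peaks was recovered with an excess of 28.9 percentage points, and 59.4% of shared peaks were recovered as 59.4%. Calculations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.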

Results

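Chromatin immunoprecipitation followed by sequencing was used to map where EFL-1 sits on the genome of Caenorhabditis elegans. EFL-1 is a member of the E2F family of transcription factors, which bind DNA with a DP partner (DPL-1 in the worm) and can act in a repressive complex, DREAM, with the Rb-like protein LIN-35. The worms were transgenic young adult hermaphrodites of the strain YL478, which carries EFL-1 with a GFP-FLAG tag at its C terminus. Chromatin of whole animals was precipitated with an antibody to GFP. There was 1 group of samples with 2 biological replicates, so the design implies a description of the sites and of the agreement between replicates, and no contrast between conditions. The authors deposited a list of 30000 regions for each replicate, a list of 30000 regions called on both replicates together, and a thresholded set, called optimal, of 2825 peaks. Signal values and ranks below are the authors' values per peak. Coordinates are on build ce11. Read depth per sample is unknown from these lists, and intervals on shares cover counting error only.

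The optimal set held 2802 peaks on the nuclear chromosomes and 23 on the mitochondrial genome, and the nuclear peaks covered 683 kb, or 0.681% of the nuclear sequence. The strongest peak lay on chromosome III from 3867229 to 3867818, with its summit 290 bp upstream of the start site of rpl-3 (WBGene00004414), a gene of the large ribosomal subunit, and had a signal value of 2554. It ranked 1 in each replicate, at 1250 in replicate 1 and 1298 in replicate 2. The next in rank were the promoter of rib-2 (III, 10742488 to 10742889, signal 2293), the promoter of the centromere protein gene hcp-1 (V, 6593673 to 6594122, signal 2074), the region 459 bp upstream of rpl-35 (signal 2011), the promoter of the histone chaperone-like gene nasp-2 (signal 1967) and the promoter of pie-1 (III, 12426586 to 12426912, signal 1937), which encodes a maternal regulator of germ cell fate. Of the 25 strongest peaks, 20 had a protein-coding start site within 500 bp, 2 were mitochondrial and 3 were nuclear peaks farther from a start site. The nearest start sites of those 3 belonged to hcp-3, the gene of the centromeric histone, at 647 bp, usp-4 at 670 bp and klp-7 at 925 bp, which were named after their values were seen. The remaining genes nearest to the strongest summits were cpg-2 (signal 1740), sgo-1 (1698), cdc-48.1 (1690), skpt-1 (1650), pygl-1 (1590), F43G6.16 (1583), mex-1 (1577), Y53F4B.11 (1529), mcm-2 (1470), klp-18 (1448), kin-35 (1401), cpg-1 (1368), tasp-1 (1360) and gpd-1 (1356). Among the 23 nuclear peaks of this group, 18 had the E2F core sequence TTSSCGC (S is C or G) within 100 bp of the summit. The peaks of rib-2, klp-18 and Y53F4B.11 also lay within 500 bp of a start site of tbb-1, cogc-2 and Y53F4B.9, respectively, and counted for both genes.

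The genes of EFL-1 itself and of its partners all had a promoter peak. At efl-1 (WBGene00001161, V, 16958590 to 16965675, minus strand) the peak from 16965749 to 16965961 was intergenic, 198 bp upstream of the start site, with a signal value of 382 and rank 222 in the optimal set. Its values were 179 in replicate 1 and 197 in replicate 2, and TTSSCGC lay within 100 bp of its summit. Another 2 optimal peaks lay in introns of efl-1, at 16963603 to 16963892 (signal 60.3) and 16964439 to 16964728 (signal 49.9). The first of these had 27.6 in replicate 1 and 22.6 in replicate 2. The second had 34.9 in replicate 2 and no region in replicate 1. The worms are transgenic for a tagged EFL-1, and the control was not analysed here. Whether the transgene itself affects the calls at the efl-1 locus was therefore not tested. At lin-35 (WBGene00003020, I, 5807709 to 5815637) the peak had a signal of 317 and rank 275, with 186 in replicate 1 and 131 in replicate 2. At dpl-1 (WBGene00001061, II, 9169910 to 9172565) the summit lay in an annotated untranslated exon 257 bp upstream of the nearest start site, with a signal of 68.2 and rank 1637. The dpl-1 peak was less alike between replicates, with 50.7 and rank 1224 in replicate 1 against 14.4 and rank 4545 in replicate 2, which is below the 2802 strongest regions of that replicate. The lin-35 and dpl-1 peaks had no TTSSCGC within 100 bp of the summit.

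The replicates were compared through their own lists, as a measure of how far the same sites were found again. The optimal peaks are the strongest regions called on both replicates together, so their shares in each replicate are partly built in. The direct comparison between replicates does not use the optimal peaks. Of the 2802 nuclear optimal peaks, 2412 (86.1%, exact 95% interval 84.7 to 87.3) overlapped one of the 2802 strongest nuclear regions of replicate 1 by at least 1 bp, and 2334 (83.3%, 81.9 to 84.7) did so in replicate 2. A total of 2003 peaks (71.5%) were among the 2802 strongest of both replicates and 59 (2.11%) of neither. For the strongest 700 optimal peaks, those of rpl-3, hcp-1, pie-1 and the rest with a signal of at least 141, the share in both was 99.7%. For the weakest 701, with signals from 40.1 to 53.3, it was 17.97%. These lie next to the cut at 2802 regions, so part of the fall is built in. Against all regions of a replicate's list, background included, 2783 of the 2802 optimal peaks overlapped one in replicate 1 and 2784 in replicate 2. Directly between replicates, 72.4% (70.8 to 74.1) of the strongest 2802 regions of replicate 1 overlapped one of replicate 2, against 1.65% on average over 1000 rotations of the positions within chromosomes (permutation p = 0.001, the smallest these can give). The shared fraction was 61.1% when 50% reciprocal overlap was required.

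Signal values of matched regions rose together in both replicates. Across the 13381 nuclear regions paired between the full lists, Spearman's rho was 0.593 and Pearson's r of the log2 signal values was 0.801 (permutation p = 1.0e-05 for each, the smallest that 100000 permutations can give). Within the optimal peaks, which were selected on the signal of both replicates together, 2775 pairs gave a rho of 0.712 and an r of 0.807. These correlations are across regions within a pair of samples, and regions are not independent replicates. Of the 48 genes with a promoter peak that the rule names from the gene lists, 43 had replicate values within a factor of 2 of each other. The other 5 were higher in replicate 1, among them the Argonaute gene csr-1 (324 against 69.3) and the Fanconi anaemia gene fcd-2 (202 against 69.4). The lists were called separately and their depth and scale are unknown, so these factors are descriptive only. Most of these genes were named for strong signal in both replicates together, which partly builds in their likeness.

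The next question was where the peaks lie relative to genes. Of the nuclear optimal summits, 1803 (64.3%) were within 500 bp of the start site of a protein-coding gene, against 23.4% on average over 1000 random placements within the same chromosomes (SD 0.801, highest 25.8%; one-sided permutation p = 0.001, the smallest these can give). The summit was upstream of the nearest start site for 1501 of the 1803, at a median distance of 177 bp. The promoter peaks of the replication genes mcm-3 and dut-1 were both 135 bp upstream, that of the oogenesis gene mex-1 184 bp upstream and that of the P granule helicase gene glh-2 2 bp upstream. By position, 1939 summits (69.2%) were intergenic, where 37.3% of the nuclear sequence lies, and 177 (6.32%) were in coding exons, which make up 24.6% of it. Introns held 474 summits (16.9%) and untranslated exons 212 (7.57%). Within 200 bp of a start site the share was 38.2%, against 10.2% for random placements. Many worm transcripts are trans-spliced, so an annotated start may lie downstream of the site where transcription begins.

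**Figure D1:**
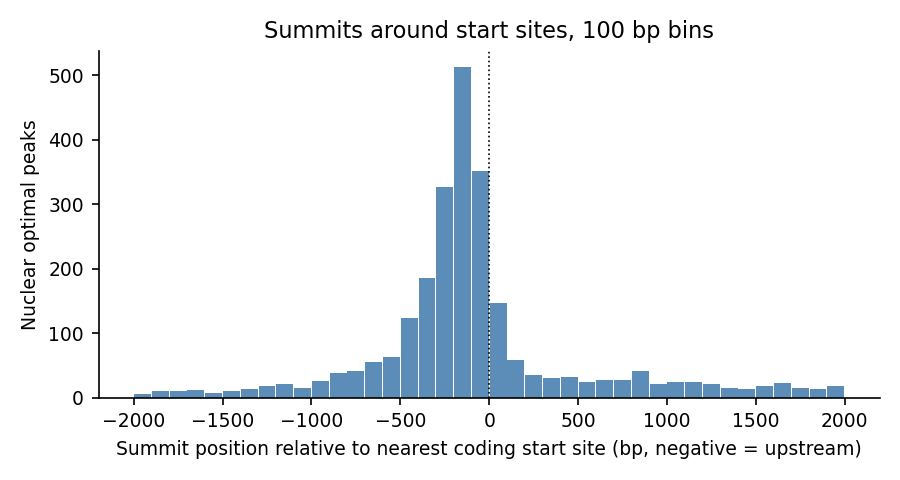
Number of nuclear optimal peaks (vertical axis) by the position of their summit relative to the nearest protein-coding start site in bp (horizontal axis, negative values upstream), in 100 bp bins. The highest bar, with 512 peaks, is the bin from 200 to 100 bp upstream.

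Promoter peaks were then counted for 16 gene lists fixed before the data were examined. A summit within 500 bp of any annotated start site was found for 2187 of 19973 protein-coding genes (10.9%). Genes of DNA replication were among those with a peak most often, with 31 of 41 members (75.6%, odds ratio 25.6 against all other genes, 95% interval 12.2 to 58.5). Their strongest peaks were at mcm-2, a subunit of the replicative helicase (signal 1470, 238 bp upstream), at pcn-1, the sliding clamp gene (1040), at mcm-3 (584) and at dut-1 (533), and each of the 4 contained TTSSCGC. No promoter peak was called at rnr-2 or orc-2. Genes of mitosis and cell cycle control had a peak in 48 of 71 cases (67.6%, odds ratio 17.3, interval 10.3 to 29.9). Here the strongest were hcp-1 (2074), the spindle kinesin gene klp-18 (1448), the Polo kinase gene plk-1 (769) and the kinetochore gene knl-3 (749), and none was called at cdk-1 or cdk-4. DNA repair and checkpoint genes had a peak in 21 of 47 cases (44.7%, odds ratio 6.62, interval 3.54 to 12.3), led by the claspin gene clsp-1 (790), by polk-1 (338) and polh-1 (316) of translesion synthesis and by fcd-2 (268), and without one at brd-1 or brc-2. The intervals of these odds ratios cover counting error only.

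Lists of germ line genes also had promoter peaks more often than other genes. Of the oogenesis and early embryo list, 36 of 59 members (61.0%, odds ratio 12.9, interval 7.44 to 22.9) had a promoter peak. Examples were pie-1 (1937), the eggshell proteoglycan genes cpg-2 (1740) and cpg-1 (1368), and mex-1 (1577), and puf-6 and lin-41 had none. The median signal of this list's promoter peaks, 407, was above that of the replication list, 199, and of the nuclear optimal peaks as a whole, 78.4; these medians were not tested. Meiotic chromosome genes had a peak in 23 of 40 cases (57.5%, odds ratio 11.1, interval 5.67 to 22.2). The strongest were the meiotic cohesin genes rec-8 (1021), coh-4 (933) and coh-3 (649) and the RING finger gene zhp-2 (520), all 4 without TTSSCGC within 100 bp, and the axis genes him-3 and htp-1 had no promoter peak. P granule and small RNA genes had a peak in 24 of 54 cases (44.4%, odds ratio 6.57, interval 3.67 to 11.6). Among them were glh-2 (1240), the Argonaute genes hrde-1 (929) and csr-1 (406), and tofu-6 (409), with none at pgl-1 or glh-1. The csr-1 summit was in an intron, 415 bp upstream of a start site inside the gene. Chromatin regulators of the germ line had a peak in 16 of 35 cases (45.7%, odds ratio 6.89, interval 3.31 to 14.2), led by isw-1 (833), the histone variant gene htz-1 (415) and the histone methyltransferase genes set-2 (371) and mes-2 (353), and mes-3 and mes-4 had none.

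Genes of the DREAM complex and the synMuv class, which includes efl-1, had a peak in 9 of 31 cases (29.0%, odds ratio 3.34, interval 1.35 to 7.55). The strongest were lin-9 (1036), lin-53 (894), lin-54 (498) and efl-1 (382), and efl-2 and lin-37 had none. TTSSCGC was in 4 of the 9 promoter peaks of this list, those of lin-9, lin-53, lin-54 and efl-1. Spermatogenesis genes had a peak in 4 of 36 cases (11.1%, against 10.9% of other genes), among them spe-39 (974), spe-47 (140) and spe-9 (46.8), and spe-4 and spe-6 had none. The spe-47 summit lay past the 3' end of the gene, 402 bp downstream of a start site. The spe-9 summit was in an intron, 427 bp upstream of a start site inside the gene. Of the 4 genes, 2 had their strongest summit upstream of a start site and 1 within 200 bp. Apoptosis genes had a peak in 3 of 28 cases (10.7%), namely psr-1 (114), the p53-like gene cep-1 (59.3) and ced-5 (50.2), and ced-1 and ced-2 had none. The psr-1 summit was in an intron, 386 bp upstream of a start site inside the gene. For these last 2 lists the odds ratios were 1.02 (interval 0.261 to 2.87) and 0.976 (0.188 to 3.202), so differences from other genes inside these intervals were not detectable. These counts depended on the replicates: spermatogenesis had 2 of 36 without replicate 1 (odds ratio 0.502) and 6 of 36 without replicate 2 (1.68), and apoptosis had 1 of 28 without replicate 2 (0.310), none of them passing.

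Ribosomal protein genes, chosen as a broadly expressed class, had a promoter peak in 61 of 78 cases (78.2%, odds ratio 29.99, interval 17.2 to 54.9). Besides rpl-3 (2554) and rpl-35 (2011) the strongest were rpl-20 (639) and rpl-24.2 (526), none of the 4 with TTSSCGC, and rpl-10 and rpl-11.2 had none. The median summit was 286 bp upstream of the start site, and 9 of the 61 genes had their strongest summit within 200 bp. Some of these peaks lie between a ribosomal gene and another listed gene, as between rpl-12 and lin-54 and between rps-22 and polh-1 (pairs picked after their values were seen), and were counted for both. With each peak given to its nearest start site alone, 39 of 78 ribosomal protein genes (50%) had a peak (odds ratio 10.6), below DNA replication at 20.4. Proteasome genes had a peak in 19 of 33 cases (57.6%, odds ratio 11.1, interval 5.28 to 24.0), led by rpn-6.1 (722), pas-6 (495), rpn-2 (345) and rpn-11 (296), and pas-1 and pas-2 had none. The rpn-6.1 summit was in an intron, 413 bp upstream of a start site inside the gene. TTSSCGC was in 8 of the 19 proteasome peaks (42.1%), the 4 strongest among them. Set against ribosomal protein genes, a comparison chosen after the data were seen, no difference passed for DNA replication (odds ratio 0.864, adjusted p = 0.819) or mitosis (0.582, adjusted p = 0.209), and the other 13 of the 15 lists had a peak less often, among them oogenesis (0.436, adjusted p = 0.0428), meiotic chromosomes (0.377, adjusted p = 0.0419) and P granules (0.223, adjusted p = 1.8e-04; Fisher's exact test). This comparison turned with the assignment of peaks. With a window of 200 bp, ribosomal protein genes had a peak less often than DNA replication (odds ratio of that list 11.98), mitosis (5.29), meiotic chromosome (4.6) and DNA repair genes (3.25), each at adjusted Fisher's exact p under 0.05, and 1 list was lower, the neuron markers. With nearest start sites 7 lists were lower, 0 were higher at that threshold, and oogenesis was at 1.19, and for the 1401 strongest peaks 8 were lower and oogenesis was at 1.17.

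Markers of somatic tissues were almost without promoter peaks. None of 36 body muscle markers (myo-1 and myo-2 among them), none of 35 intestine markers (vit-1 and vit-2) and none of 40 hypodermis and cuticle markers (dpy-2 and dpy-3) had a promoter peak. Of 57 neuron markers 1 did, tdc-1 (signal 164), while unc-17 and cha-1 did not. Together, a grouping made after the data were seen, 1 of 168 somatic markers had a peak (0.595%, exact 95% upper limit 3.27%), against 11.0% of other genes. Chromatin came from whole animals, which mix tissues, so binding limited to a single tissue may go uncalled. The lack of a called peak is therefore not evidence that EFL-1 is absent from these genes in their own tissue.

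Two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 16 lists gave 10 lists with more peaks than other genes, with adjusted p from 1.8e-42 for ribosomal proteins to 0.00763 for the DREAM and synMuv list. They gave 4 lists with fewer, with adjusted p of 0.0329 for muscle and intestine and 0.0254 for neuron and hypodermis. With a window of 200 bp, in the same Fisher's exact test, the ribosomal protein list (9 of 78, odds ratio 2.08, adjusted p = 0.0786) and the DREAM and synMuv list (odds ratio 1.70, adjusted p = 0.489) no longer passed, and the calls of the single somatic lists were lost under several settings, where their odds ratios were 0 to 0.257. On autosomes alone, with 24 of the 36 muscle markers left, the hypodermis list was the 1 that passed, the odds ratios were 0 for muscle and intestine and 0.175 for neuron markers, and the joint somatic group was at 0.0589 (Fisher's exact p = 4.3e-06).

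**Figure D2:**
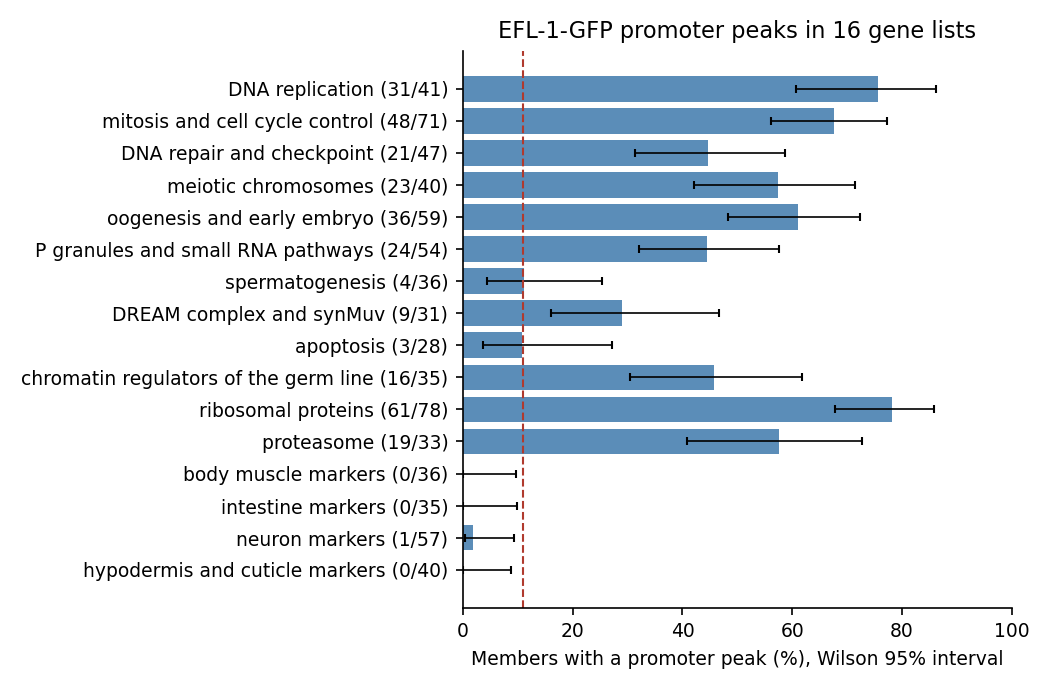
Share of each list's members with an EFL-1-GFP promoter peak in percent (bars, horizontal axis) with Wilson 95% intervals (lines); the dashed line marks the 10.9% of all protein-coding genes. Bars of 10 lists stand above the line at adjusted p under 0.05, and the bars of muscle, intestine and hypodermis markers are at 0.

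Promoter peaks were unequal between chromosomes, and the X had the fewest. A promoter peak was found for 32 of 2731 X-linked genes (1.17%), against 12.5% of autosomal genes (odds ratio 0.0830, 95% interval 0.0565 to 0.118; two-sided Fisher's exact test, p = 1.5e-101, adjusted over 6 chromosomes 8.8e-101). The strongest X-linked promoter peak was at mrp-4 (9883949 to 9884161, signal 262), a gene chosen after its values were seen. Among members of the lists other than the somatic and spermatogenesis ones, 3 of 21 X-linked genes had a peak, meg-1 (signal 108), meg-3 (41.4) and meg-4 (42.2), which encode P granule proteins of the embryo and were also singled out afterwards. The meg-1 region had rank 1961 in replicate 1 and 610 in replicate 2. The meg-3 region ranked 6357 in replicate 1, below its 2802 strongest, and 2097 in replicate 2. At meg-4 replicate 1 had no region, and the rank in replicate 2 was 2548. Chromosomes I (18.3% of genes, odds ratio 2.08) and III (18.7%, odds ratio 2.12) stood above the rest, and V below it (6.61%, odds ratio 0.50, Fisher's exact test, adjusted p = 2.5e-32). The adjusted p was 8.1e-37 for I and for III, and 0.0371 for II (odds ratio 1.13) and 0.0468 for IV (odds ratio 1.13). The X odds ratio was 0.0475 without replicate 2 and 0.116 without replicate 1, and it was 0.0410 for the 1401 strongest peaks, 0.105 with a window of 1000 bp and 0.104 with nearest start sites.

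**Figure D3:**
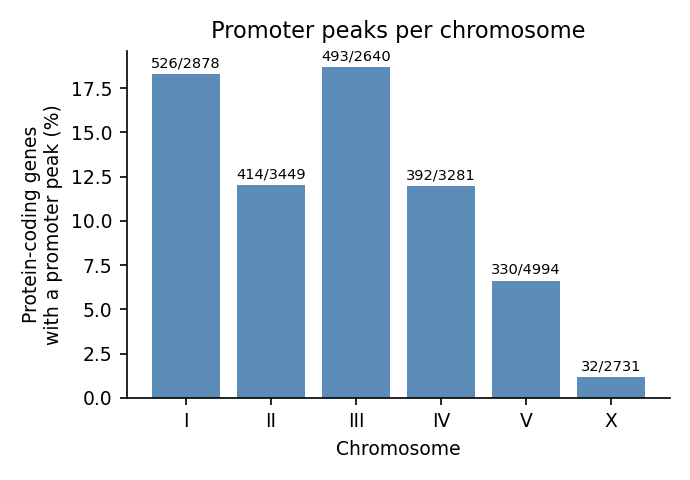
Share of protein-coding genes with a promoter peak in percent (vertical axis) on each nuclear chromosome (horizontal axis), with the number of genes with a peak over the number of genes above each bar. Chromosome III is highest at 18.7% and the X lowest at 1.17%.

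Within autosomes, genes in the chromosome centres had promoter peaks slightly more often than genes on the arms. In the middle 33.3% of the length of each autosome 886 of 6570 genes (13.5%) had a promoter peak, against 1269 of 10672 (11.9%) outside it (odds ratio 1.16, 95% interval 1.05 to 1.27; two-sided Fisher's exact test, p = 0.00222). The call was lost for the 1401 strongest peaks (odds ratio 1.06, Fisher's exact p = 0.311) and within 200 bp of start sites (odds ratio 1.06, p = 0.383).

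The sequence under the summits was examined for the E2F core site and for the cell cycle homology region (CHR), an element contacted by DREAM in textbook accounts. TTSSCGC occurred within 100 bp of the summit in 832 of 2802 nuclear optimal peaks (29.7%, Wilson 95% interval 28.0 to 31.4) and in 210 of their flanks of the same width (7.49%), with 761 peaks having it at the centre alone and 139 in the flank alone (exact two-sided binomial test, p = 1.7e-104). Among the 630 orderings of the same letters, TTSSCGC had the largest excess over the flanks, 22.2 percentage points, with 18.7 points for the next ordering, SCGCSTT, and a median of 0.607 over the others. The CHR sequence TTYGAA (Y is C or T) occurred in 58.5% of centres and 49.1% of flanks (exact p = 6.6e-13), an excess of 9.31 points that also ranked 1 among 180 orderings. The positions differed: TTSSCGC was most frequent in the 20 bp on either side of the summit (7.42% and 7.28% of peaks), and TTYGAA was less frequent there (6.46% and 6.67%) than 20 to 40 bp away (9.89% and 10.8%). Without replicate 1 the TTYGAA excess was 5.50 points, and the longer TTTSSCGC had an excess of 13.1 points.

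The E2F core was more frequent in stronger peaks. It was found in 354 of the 700 strongest peaks (50.6%), the group of mcm-2, pcn-1 and lin-9, and in 122 of the 700 weakest (17.4%), an odds ratio of 4.85 (95% interval 3.77 to 6.25; two-sided Fisher's exact test, p = 5.1e-40). For TTYGAA the shares were 67.7% and 53.4% (odds ratio 1.83, Fisher's exact p = 5.8e-08). By gene list, TTSSCGC was present in 24 of 34 promoter peaks of DNA replication genes (70.6%, Wilson 95% interval 53.8 to 83.2), 30 of 50 of mitosis genes (60.0%, 46.2 to 72.4), 22 of 39 of oogenesis genes (56.4%, 40.98 to 70.7), 6 of 23 of meiotic chromosome genes (26.1%, 12.5 to 46.5) and 7 of 62 of ribosomal protein genes (11.3%, 5.58 to 21.5).

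**Figure D4:**
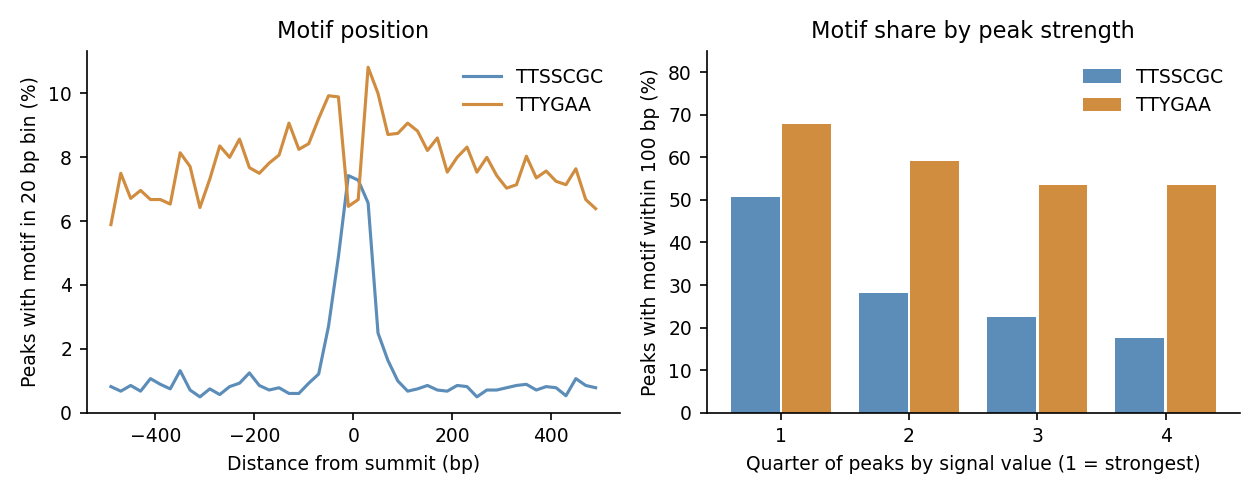
Left, share of nuclear optimal peaks in percent with TTSSCGC or TTYGAA in each 20 bp bin (vertical axis) by distance from the summit in bp (horizontal axis). Right, share of peaks in percent with each motif within 100 bp of the summit (vertical axis) for the peaks split into 4 equal parts by signal value (horizontal axis, 1 is strongest), where TTSSCGC goes from 50.6% to 17.5%.

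All 7-mers were then compared between the 50 bp on either side of the summits and flanks of the same width. Of 8192 7-mers, 861 were more frequent at the summits and 738 less frequent at an adjusted p under 0.05 (exact binomial test, Benjamini-Hochberg). The 10 with the lowest p were CGCGCGC (7.85% of peaks against 0.178% of flanks, adjusted exact p = 1.4e-54), CGAGACC (10.8% against 1.46%), AACGCGC (7.42% against 0.357%), GCGAGAC (8.17% against 0.785%), GCGCGAA (8.28% against 0.857%), AGCGCGC (6.57% against 0.321%), AAGGCGC (9.46% against 1.36%), CGCGCTC (8.07% against 0.928%), GCGCGCA (6.28% against 0.321%) and AAACGCG (7.49% against 0.892%). Of these 10, 1 matches TTSSCGC on either strand, 7 contain SSCGC or its reverse complement and 9 contain CGC or GCG. Overlapping 7-mers are not independent, and the summits had a GC content of 39.01% against 37.6% in the flanks.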

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

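The tests of read depth on the mitochondrial genome and on the X, of the motif as the source of all mitochondrial peaks, of gene class on the X with the list held fixed, and of highly transcribed and of open promoters were chosen after the pattern they bear on was seen. The design has 1 group, so no biological explanation that compares groups was tested.

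The mitochondrial genome, which no comparison uses, held 23 optimal peaks, which are listed here as signal outside the comparisons; whether that number is more than expected was not tested. The strongest of them lay at 4310 to 5188 with a signal of 1670 and rank 12, and 23 of the 23 overlapped a region of replicate 1 and 21 a region of replicate 2. The mitochondrial genome holds TTSSCGC at 1 place, within 100 bp of the summit of 1 of the 23 peaks, so a test of the E2F motif at mitochondrial peaks against their flanks could show nothing, but 22 peaks lack the motif, which argues against it as the source of all of them. The optimal peaks covered 42.8% of the mitochondrial genome, a share 62.9 times that of the nuclear genome, and 23 of the 25 mitochondrial regions of the joint list passed the threshold. Uneven read depth on a genome present in many copies is a candidate explanation that these values leave open.

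Few promoter peaks were found on the X. Fewer E2F motifs in X promoters cannot account for it alone: among genes with TTSSCGC within 500 bp of a start site, 21 of 717 on the X and 1059 of 5161 on autosomes had a peak (odds ratio 0.117, 95% interval 0.0715 to 0.181). Among members of the lists other than the somatic and spermatogenesis ones 3 of 21 X-linked and 287 of 493 autosomal genes had a peak (odds ratio 0.120, interval 0.0224 to 0.419), but these differ in class, and with the list held fixed the common odds ratio over 6 lists was 0.193 (interval 0.0333 to 0.752, exact p = 0.0095; 3 observed and 8.20 expected), which argues against gene class for these genes, although the P granule list alone had 3 of 6 on the X and 21 of 48 on autosomes. Of the X-linked P granule peaks, those of meg-3 and meg-4 were not among the 2802 strongest regions of replicate 1. The listed genes are 0.769% of X-linked genes, so gene class stays open for the others, and the X also held 5.61% (Wilson 95% interval 4.84 to 6.49) of the 2997 weakest nuclear regions of the joint list, less than 8.84%, which is 50% of its share of sequence. A lower sensitivity of calling on the X, or less signal of any kind there, may therefore contribute and stays open, as does the state of the X in germ cells, which these lists do not measure.

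Most ribosomal protein promoters had a peak. TTSSCGC within 100 bp of the summit does not account for most of these peaks, since it was in 7 of 62 of them. In the DNA replication and mitosis peaks it was in 52 of 82, leaving out 1 peak shared by both groups (odds ratio of the ribosomal protein peaks 0.0734, 95% interval 0.0255 to 0.192, Fisher's exact p = 9.5e-11). At the ribosomal protein peaks its share was 11.3%, against 3.23% in their flanks (exact binomial test, p = 0.125). Other forms of the E2F site, and sites farther from the summit, were not counted in these promoters and stay open. A signal of all highly transcribed promoters stays open. The share of somatic markers with a peak has an upper exact limit of 3.27% against 11.0% of other genes. However, transcription was not measured here, and whole animals mix tissues, so a signal limited to a single tissue may go uncalled. In addition, tRNA genes had 97 summits within 200 bp against 4.74 in random placements. Whether promoters open in germ cells give such peaks in general cannot be told apart from occupancy by EFL-1, because 49.03% of the peaks of listed germ line and cell cycle genes also lack TTSSCGC and no control immunoprecipitation was analysed here.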

How the results depend on the processing

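The outermost start site, the joint group of somatic lists and the comparison with ribosomal protein genes were chosen after seeing the data. The strongest 2802 nuclear regions of the joint list are the optimal peaks themselves, so that alternative is void. The promoter share (38.2% to 77.5%), the X odds ratio (0.0410 to 0.116), the E2F excess (13.1 to 32.1 points), the CHR excess (5.50 to 13.6 points), the E2F motif odds ratio by peak strength (2.60 between the stronger and weaker 1401), the rank agreement (rho 0.705 to 0.712) and the number of optimal peaks (2853 on ce10, 2811 after merging overlapping peaks) kept their direction and, where tested, their side of the threshold in every alternative run. The number of lists with more peaks than other genes was 8 with a window of 200 bp and 10 otherwise. The replicate overlap was 61.1% with 50% reciprocal overlap, 67.7% with summits within 100 bp and 78.4% for the strongest 1401 regions; the first 2 rules are stricter by construction. The odds ratio of chromosome centres was 1.06 for the 1401 strongest peaks and 1.06 with a window of 200 bp, where it no longer passed, and between 1.11 and 1.28 otherwise; the cause was not tested. The number of lists with fewer peaks, 4 in the report, was 1 on autosomes alone, 0 for the 1401 strongest peaks, 0 with a window of 200 bp, 0 with nearest start sites and 2 to 3 when either replicate was left out; the first of these settings has fewer members and the next 3 fewer bound genes by construction, and for the others the cause was not tested. The joint group of 168 somatic markers passed in every alternative (odds ratio 0 to 0.113). Among single lists with lost calls, the odds ratio was 2.08 for ribosomal proteins and 1.70 for DREAM and synMuv genes with a window of 200 bp, where the summits of these lists lie mostly farther out (9 of 61 and 3 of 9 genes within 200 bp). It was 0.175 on autosomes alone, 0.257 for the 1401 strongest peaks, 0 with a window of 200 bp and 0.186 with nearest start sites for neuron markers. For muscle markers the call was lost without replicate 1, where 1 of 36 had a peak (0.244), and not without replicate 2 (0), and for intestine markers it was lost without either (0 in both). It was 0 in the remaining cases. Of 15 lists compared with ribosomal protein genes, 13 were lower in the report, 8 for the 1401 strongest peaks, 7 with nearest start sites, 1 with a window of 200 bp and 13 in the other settings. Nearest start sites lowered the odds ratio of ribosomal proteins from 29.99 to 10.6. The number of 7-mers more frequent at summits was 861, and that of 6-mers 442, of which fewer exist. No paired analysis was possible because there is 1 group. Depth is unknown, and 17.97% of the weakest 701 optimal peaks were among the 2802 strongest regions of both replicates. This limits statements on single weak peaks, although part of it is built in by the cut at 2802 regions.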

Other observations

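The tests of genes for short RNAs, of peak strength and of oogenesis peaks were chosen after the data were seen. Outside the fixed lists, 159 families of gene names with at least 10 members were tested, and 10 had promoter peaks more often than other genes at an adjusted p under 0.05 (Fisher's exact test). The nucleoporin family npp had a peak in 17 of 26 cases (65.4%, adjusted exact p = 4.1e-09), with npp-3 at a signal of 1205, npp-9 at 492 and npp-8 at 299. The families of RNA polymerase subunits rpb (8 of 11), translation initiation factors eif (13 of 25), cytochrome oxidase cox (8 of 15), RNA-binding proteins rbm (7 of 13), madf (5 of 10), sec (8 of 19), cdc (5 of 12), mitochondrial ribosomal proteins mrpl (13 of 41) and dnj (9 of 29) also passed. Another 21 families had peaks less often, among them the nuclear hormone receptors nhr (1 of 267), the chemoreceptor families str (0 of 192) and srh (1 of 220), the C-type lectins clec (3 of 238) and the collagens col (4 of 147). The genes were named after their values were seen. The hypothesis written before the test was that families of gene name prefixes beyond the fixed lists would be found among bound genes. It asked for at least 1 such family, and the 10 found meet it. With 159 families tested this is a low bar, so the result describes these families and lends little support beyond that.

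Genes for short RNAs made up a further group. Of the nuclear optimal summits, 97 were within 200 bp of the start of a tRNA gene, against 4.74 on average over 1000 random placements (SD 2.201), 78 near snoRNA genes against 4.42, 24 near snRNA genes against 1.53 and 11 near miRNA genes against 2.43 (adjusted permutation p = 0.0020 for each of these 4, over 8 classes). The tRNA peaks were weak, with a median signal of 50.5 and a highest of 89.6, and 8 of the 97 had TTSSCGC. For piRNA genes the number was 31 against 92.6. CGAGACC, the 7-mer without CGC or GCG among the 10 lowest p, was within 50 bp of the summit in 33.9% of the ribosomal protein peaks and 11.0% of the replication and mitosis peaks.

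Genes with a promoter peak had the start site of an opposite-strand gene within 1000 bp upstream in 44.1% of cases, against 14.4% of other genes (odds ratio 4.67, 95% interval 4.25 to 5.14, Fisher's exact p = 6.9e-209). Part of this follows from counting a peak for both neighbours, and with assignment to the nearest start site the shares were 31.9% and 16.3% (odds ratio 2.40, interval 2.15 to 2.68). A preference for shared promoters of divergent gene pairs is a hypothesis these values leave standing. Promoter peaks of the DNA replication and mitosis lists had TTSSCGC in 53 of 83 cases (63.9%, with the 1 peak shared with a ribosomal protein gene included), against 516 of 1720 other promoter peaks (30%; odds ratio 4.12, interval 2.55 to 6.76, Fisher's exact p = 6.8e-10). These peaks were also stronger (median signal 178 against 86.3), and with the tenth of signal among promoter peaks held fixed the common odds ratio was 3.04 (interval 1.81 to 5.16, exact p = 9.8e-06), which argues against peak strength as the whole cause. Oogenesis peaks had the motif in 22 of 39 cases (odds ratio of cell cycle against oogenesis peaks 1.37, interval 0.581 to 3.17, Fisher's exact p = 0.434), so whether the motif content is particular to cell cycle genes stays open. Stronger motif content at cell cycle promoters than at the other bound promoters as a group is thus a hypothesis.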
